A study of Mus musculus with 3 samples.

How the data were processed

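Single-cell RNA sequencing was measured in cells of mouse femoral arteries. Per the labels, 8-week-old wild-type male mice had a wire-induced injury of the femoral artery or a sham operation, and the injured arteries were taken 2 or 7 days later. The labels give no time of harvest for the sham arteries. Per the labels, cells were stained with DAPI, a dye that enters dead cells, live single cells were sorted by flow cytometry, and those of 6 mice were pooled into 1 droplet library per group (Sham, D2 and D7) with the Chromium Single Cell 3' v3 chemistry. The deposited matrices hold raw UMI counts (unique molecular identifiers, 1 per captured transcript) per gene and barcode, which was checked on the values, all of them whole numbers. Per the file headers they came from Cell Ranger 7.1.0, whereas the submitters' processing notes name Cell Ranger 7.2.0 with the mm10 genome and Seurat 5.0.1. The files analysed here hold no cell annotation, so cell classes were rebuilt from the counts. Every deposited barcode holds at least 500 UMIs, so cells with fewer had left the data before.

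Each of the 3 matrices lists 32285 genes. Barcodes with at least 300 genes, at least 500 UMIs and at most 15% mitochondrial UMIs were kept, which removed 306 Sham, 217 D2 and 363 D7 barcodes. Scrublet, as implemented in scanpy 1.11.5 and run per library with an expected doublet rate of 8%, then removed 79 (1.06%), 485 (4.23%) and 228 (2.03%). Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes gave 30 principal components, a graph of 15 neighbours and 43 Leiden clusters at resolution 1 over all libraries together (leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, Python 3.11.15). No batch correction was made, since library and group are the same thing here.

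A cluster was named from 154 markers fixed for 16 classes. A class scored by the mean, over its markers, of the z score over clusters of log2(CPM + 10), taken relative to the highest score any cluster reached. The cluster took the best-scoring class with at least 3 markers detected in 10% of its cells and a relative score of at least 0.3, provided that its 10 leading genes held no more genes of another class than of this one. A class with none of its genes among them needed a score of 0.6. A cluster with a median depth more than 3-fold below that of its libraries also needed a marker of the class among its leading genes. These thresholds, and extra genes used only to read the leading genes (among them Lef1, Tox, Skap1, Themis and Camk4 for T cells and Itgb4, Cldn1 and Lypd2 for perineurial cells), were set after the clusters had been seen. In this way 38 clusters were named and 5 stayed without a class. Class names are written with "-like" because they rest on transcripts alone.

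UMIs were summed per class and library and given in CPM, the counts scaled to the same total in every sum. Shares of cells carry exact Clopper-Pearson intervals, CPM values exact Poisson intervals and ratios of CPM exact conditional binomial intervals, all at 95.0%. Where the report gives a share of 0, the limit beside it is the share that 3 counts would make, which is lower than the Clopper-Pearson bound. With 1 library per group no test between groups was possible, and none was made. All intervals cover counting error only, not differences between mice, operations, dissociations or sorts. Those of CPM and of CPM ratios treat every UMI as independent and so leave out differences between cells of a class. They are too narrow where few cells hold most of the UMIs. A class was compared where both libraries held at least 50 of its cells. A gene counted as apart in a pair of libraries if it had at least 50 CPM and 20 UMIs in the higher one and a ratio of (CPM + 1) of at least 2, which describes these libraries and is no count of tested genes. Genes with 0 UMIs in one library were set at 3 counts there, over the summed class, and their fold is given as a lower bound.

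The genes named in the text follow a rule fixed before the data were examined, as were the gene lists, the markers, the comparisons and all alternatives but one. For each of 4 classes (fibroblast, smooth muscle, endothelial, monocyte/macrophage) the rule took the 5 highest and 3 lowest genes by ratio of (CPM + 1) for D2 over Sham and D7 over D2, and the 3 highest and 2 lowest for D7 over Sham. They were drawn from genes with at least 100 CPM and a UMI in at least 10% of cells of the higher library, whose level there was at least 0.25 of that in any other named class, a guard against RNA released from other cells. Mitochondrial, ribosomal, haemoglobin, sex-linked and predicted genes were left out. Il33, Il1rl1 and Arg1 were added in every class, and up to 4 members per described list with the largest ratio among those with at least 50 CPM. Some genes that this rule named are not reported here.

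Of 421 genes in 27 lists, 418 were found. A list member was measured in a class if it had at least 10 UMIs over both libraries. For each list the median log2 ratio of (CPM + 1), the number of members at least 1.5-fold higher or lower, and the percentile of the median among 10000 random lists of equal size, matched on mean CPM in 20 bins, were computed. These percentiles describe the libraries and are not tests. The median was also taken with members at 0 UMIs set to their 3-count bound, and is given where it differs by 0.05 or more. For shares of cells with a UMI of a gene, every cell was thinned to 1000 UMIs and shallower cells were left out, with the unthinned share beside it. Gene positions are from the GENCODE annotation of the mouse build that mm10 names.

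The procedure was tested on simulated data drawn from the real counts of each compared pair, with 200 genes made 3-fold or 4-fold different. These were picked among genes with a mean of at least 100 CPM over both libraries. For fibroblast-like cells the 3 comparisons considered 3459 (D2 over Sham), 3335 (D7 over Sham) and 3389 (D7 over D2) genes, for smooth-muscle-like cells 3550 (D7 over Sham), for endothelial-like cells 3831, 3824 and 3796, and for monocyte/macrophage-like cells 3406, 3349 and 3267. All simulated 3-fold and 4-fold genes were found in each of these 10 comparisons, and no unaltered gene was counted except 1 in smooth-muscle-like cells. The intervals held the true ratio for 95.5%, 95.5% and 96.0% of the altered genes in fibroblast-like cells, 98.0% in smooth-muscle-like cells, 96.0%, 96.0% and 94.5% in endothelial-like cells and 94.0%, 95.0% and 94.5% in monocyte/macrophage-like cells. A simulated list of 15 genes at 4-fold gave median folds of 4.08, 3.79 and 4.04 in fibroblast-like, 4.10 in smooth-muscle-like, 3.89, 4.08 and 4.10 in endothelial-like and 4.16, 3.90 and 4.01 in monocyte/macrophage-like cells. The simulation adds counting error only, so it says nothing about differences between animals or between cells of a class. Nor does it show how well altered genes near the minimum of 50 CPM, or list members with few UMIs, are found.

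Alternatives recomputed the results with stricter cell filters (at least 500 genes and 1000 UMIs, or at most 10% mitochondrial UMIs), doublets kept, a class given to each cell from its markers without clusters, resolutions 0.5 and 2, each library clustered on its own, median-of-ratios scaling, the mean over cells of each cell's CPM, free RNA subtracted (the library's profile times a share estimated from neutrophil, haemoglobin and immunoglobulin transcripts), a pseudocount of 10 CPM, other minimum levels, and thinning to 2000 UMIs or none. One more, leaving out the low-depth fibroblast-like cluster of the Sham library, was chosen after seeing the data. The free RNA share was estimated at 24.0%, 2.68% and 14.2% in fibroblast-like cells of Sham, D2 and D7. It was 100% in Sham B-like cells, whose marker Igkc is among the transcripts used. In Sham fibroblast-like cells Hbb-bs stood at 285.1 CPM and S100a8 at 10.8 CPM, against 250.2 and 796.1 CPM in the whole library. The estimate thus depends on the transcript, and the subtraction may remove too much from Sham.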

Results

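Cells of the femoral artery were profiled by droplet single-cell RNA sequencing after a sham operation (Sham) and 2 days (D2) and 7 days (D7) after wire injury, a procedure that strips the endothelium and stretches the arterial wall. There was 1 library per group, each a pool of cells from 6 mice, so no difference between groups could be tested. Values are given with intervals for counting error only. The libraries held 7757 (Sham), 11690.0 (D2) and 11574 (D7) barcodes with 39756684, 98260210.0 and 100571340.0 UMIs in all. After filtering and removal of called doublets 7372, 10988 and 10983 cells were kept, with medians of 4096.5, 6625.5 and 6777 UMIs and 1722.5, 2305 and 2356 genes per cell. All levels are UMI counts summed per cell class and library, in CPM (counts scaled to the same total in every sum).

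The first question was which cells made up the artery before and after injury, and the largest differences were between stromal and immune cells. Fibroblast-like cells made up 51.7% of Sham cells (95% interval 50.5 to 52.8), 1.02% of D2 cells (0.840 to 1.23) and 28.8% of D7 cells (28.0 to 29.7). Neutrophil-like cells went the other way, with 2.01% (1.70 to 2.35), 41.0% (40.1 to 42.0) and 14.2% (13.5 to 14.8). Monocyte/macrophage-like cells made up 15.2% (14.3 to 16.0), 39.3% (38.4 to 40.3) and 26.0% (25.2 to 26.9). Immune classes together held 32.5% of Sham, 94.5% of D2 and 60.4% of D7 cells.

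As ratios, the fibroblast-like share was 50.7-fold lower at D2 than in Sham (42.0 to 61.8), and at D7 it stood at 0.557 of Sham (0.531 to 0.584). Endothelial-like cells made up 6.44%, 0.810% and 3.56% of Sham, D2 and D7 cells, 0.126 of the Sham share at D2 (0.0991 to 0.158) and 0.553 at D7 (0.482 to 0.633). Of them, 76.4%, 78.7% and 68.3% lay in cluster 15, with Fabp4, Flt1, Gpihbp1 and Plvap among its leading genes. Whether they lined the lumen of the artery or small vessels of its wall was not determined. Smooth-muscle-like cells made up 2.06%, 0.146% (16 cells) and 2.70%, a ratio to Sham of 0.0706 at D2 (0.0394 to 0.118) and of 1.31 at D7 (1.08 to 1.61). All lay in cluster 22, led by Rgs5, a pericyte marker of the fixed set, with Acta2, Tagln and Myh11. No cluster was named pericyte, so the class may hold pericytes of small vessels as well as contractile cells of the media. The smooth muscle ratios differed between the cell and class settings. At D2 the ratio was 0.4396 with at least 500 genes and 1000 UMIs per cell, 0.412 with each library clustered on its own, 0.263 with a class given to each cell and 0.03145 at resolution 2, and at D7 it turned over, at 0.773 with a class given to each cell, 0.708 at resolution 2 and 0.974 with the shallow cluster 2 left out. Lymphatic-endothelial-like cells made up 4.33%, 0.273% and 1.26%. The neutrophil-like share was 20.4-fold (17.4 to 24.2) and 7.06-fold (5.96 to 8.42) that of Sham at D2 and D7, and the monocyte/macrophage-like share 2.60-fold (2.43 to 2.78) and 1.72-fold (1.60 to 1.84), the former being 4.298-fold with a class given to each cell. Dendritic-like cells held 3.70%, 7.81% and 4.59%, T/NK/ILC-like cells (T, natural killer and innate lymphoid cells) 6.82%, 2.95% and 8.47%, B-like cells 3.77%, 3.31% and 6.85%, and mast/basophil-like cells 1.02%, 0.109% and 0.291%.

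Among non-immune cells alone, 79.3% of Sham, 44.1% of D2 and 77.9% of D7 cells were fibroblast-like, and 9.88%, 35.04% and 9.63% were endothelial-like. Different clusters carried the classes. Fibroblast-like cells of Sham came mostly from clusters 2 (51.5%), 10 (25.7%) and 12 (22.3%), those of D2 from cluster 6 (67.0%) and those of D7 from clusters 4 (44.5%) and 6 (39.7%). Monocyte/macrophage-like cells came from clusters 16 (56.5%) and 14 (26.1%) in Sham, 3 (39.2%) and 8 (20.9%) at D2, and 7 (23.3%) and 17 (21.5%) at D7. Of the cells in cluster 4, 1406 of 1409 were from D7, and of those in clusters 2 and 16, 1964 of 2119 and 631 of 698 were from Sham, so library and cell state are not separable there. Clusters without a class held 2.33%, 3.14% and 2.63% of Sham, D2 and D7 cells. Cluster 2 was shallow, with a median of 838.5 UMIs in Sham, and with it left out, a choice made after seeing the data, the fibroblast-like share at D7 was 0.817 of Sham.

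The shares rest on classes rebuilt from transcripts, on removal of 1.06%, 4.23% and 2.03% of cells as doublets, on sorted live single cells, on barcodes with at least 500 UMIs, and on depths that differed between groups, with medians for fibroblast-like cells of 1873 (Sham), 8927.5 (D2) and 11956 (D7) UMIs. With only 112 fibroblast-like, 89 endothelial-like and 16 smooth-muscle-like cells at D2, stromal values at that time rest on few cells, and at resolution 2 the fibroblast-like ratio to Sham was 0.0305 at D2 and 0.975 at D7.

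**Figure D1:**
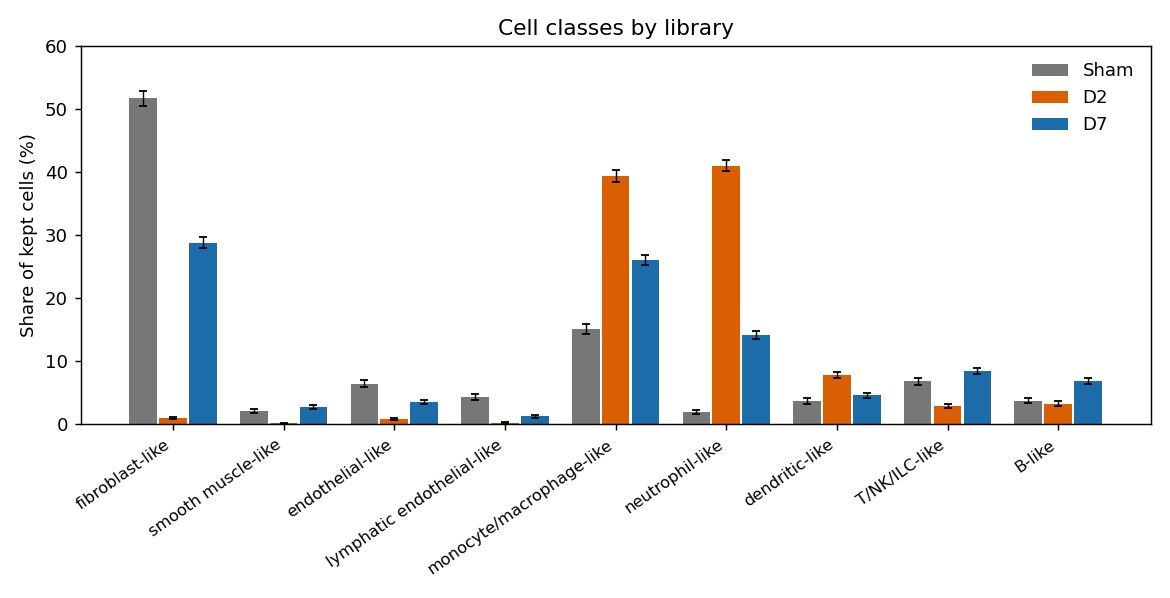
Share of kept cells (%, linear axis) in 9 rebuilt cell classes in the Sham, D2 and D7 libraries, with exact 95% binomial intervals for counting error and 1 library per group. Fibroblast-like cells stand at 51.7% in Sham against 1.02% at D2, and neutrophil-like cells at 2.01% against 41.0%.

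The series title names mesenchymal IL-33, so the second question was where Il33 (ENSMUSG00000024810, mm10 chromosome 19, 29925114 to 29960718), which encodes an alarmin cytokine held in the nucleus, and its receptor gene Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415), which encodes ST2, were detected. Il33 was found mostly in fibroblast-like cells, which held 94.6% of its UMIs in Sham, 77.9% at D2 and 97.8% at D7. At D2 clusters without a class held 9.24% of them, with cluster 23 at 117.7 CPM, and monocyte/macrophage-like cells 8.98%, and in Sham cluster 39, also without a class, stood at 278.9 CPM (185 to 403, 28 UMIs in 58 cells). Its level in them was 127.5 CPM in Sham (122 to 133), 472 CPM at D2 (442 to 503) and 472.4 CPM at D7 (466 to 479), a ratio to Sham of 3.70 (3.42 to 4.003) and 3.71 (3.54 to 3.88), and of 1.00 between D7 and D2 (0.937 to 1.07). In the whole library, where the lower share of fibroblast-like cells counts too, Il33 stood at 56.7, 13.1 and 194.7 CPM, 0.231 of Sham at D2 (0.215 to 0.248) and 3.43-fold at D7 (3.28 to 3.59).

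With every cell thinned to 1000 UMIs, an Il33 UMI was found in 11.1% of Sham fibroblast-like cells (9.94 to 12.4), 33.0% at D2 (24.1 to 43.0) and 32.0% at D7 (30.4 to 33.7). Thinning left out 1287, 9 and 148 shallower cells, and the unthinned shares were 25.7%, 77.7% and 80.1%. B-like cells, which should lack Il33, had it in 0 of 277, 0 of 359 and 0 of 746 thinned cells, which allows up to 1.08%, 0.836% and 0.402%, and in 0.360%, 0.275% and 0.399% of unthinned cells. Their median depths were 4108.5, 4550.0 and 3479.5 UMIs, against 1873, 8927.5 and 11956 in fibroblast-like cells. With fibroblast-like cells thinned to 2000 UMIs instead, the Il33 shares were 20.3% (Sham), 64.0% (D2, 53.18 to 73.95, 89 cells) and 49.9% (D7, 47.98 to 51.73). Both stayed above Sham, but how D2 stood to D7 depended on the depth. In smooth-muscle-like cells Il33 stood at 3.71 CPM (3 UMIs) in Sham and 30.9 CPM at D7, 8.33-fold apart (2.77 to 41.0). Both levels lay below those of the whole library, 56.7 CPM in Sham and 194.7 CPM at D7. The estimated share of free RNA in this class at D7 was 6.77%, so Il33 RNA from fibroblast-like cells was not excluded. Endothelial-like cells had 8.83, 4.22 and 8.05 CPM, ratios to Sham of 0.478 (0.154 to 1.27) and 0.912 (0.462 to 1.83), so no difference was detectable at this depth. Monocyte/macrophage-like cells had 1.13, 2.14 and 2.93 CPM.

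Il1rl1 was highest in mast and lymphoid cells. T/NK/ILC-like cells held 46.8%, 35.2% and 39.6% of its UMIs in Sham, D2 and D7, at 221.3, 70.4 and 50.04 CPM, and mast/basophil-like cells 25.9%, 21.2% and 18.5%, at 1424, 1461 and 998.7 CPM. Neutrophil-like cells held 18.1% at D2, at 4.08 CPM against 4.99 CPM in the whole library. RNA from other cells was thus not excluded there. Fibroblast-like cells held 13.9% at D2 and 18.9% at D7, where 89 of their 135 UMIs lay in the 242 cells of cluster 28. Within the lymphoid class the signal sat in cluster 29, led by Gata3, Il2ra and Calca, genes of group 2 innate lymphoid cells, with 120 Sham, 12 D2 and 42 D7 cells and 936.4 CPM in Sham against 743.8 CPM at D7. Over the whole library Il1rl1 was 8.89-fold lower at D2 than in Sham and 6.02-fold lower at D7, at 44.3, 4.99 and 7.36 CPM, and with the mean over cells the ratios to Sham were 0.162 and 0.271. In monocyte/macrophage-like cells it stood at 25.0, 0.420 and 3.30 CPM, and in dendritic-like cells at 66.3, 3.02 and 2.14 CPM. Thinned, 11.3%, 3.41% and 3.01% of T/NK/ILC-like cells had an Il1rl1 UMI (unthinned 25.3%, 4.94% and 6.99%), and so did 70.3% of mast/basophil-like cells in Sham and 35.5% at D7 (unthinned 93.3% and 56.3%). The mast/basophil mix differed, however, with 62 of 75 Sham but 11 of 32 D7 cells in cluster 37, led by the mast cell gene Mcpt4, and 21 D7 cells in cluster 40, led by basophil genes such as Mcpt8, at 116.1 CPM against 1828 CPM in cluster 37 of Sham. Fibroblast-like cells had 1.67, 32.0 and 3.45 CPM, 19.2-fold higher at D2 than in Sham (12.1 to 31.4). Of the 63 UMIs behind the D2 value, 55 lay in 3 cells, and the ratio was 2.27 with at least 500 genes and 1000 UMIs per cell.

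Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) encodes arginase 1, an enzyme of reparative macrophages that uses up arginine. In monocyte/macrophage-like cells it stood at 0.501 CPM in Sham (4 UMIs), 456 CPM at D2 and 307.5 CPM at D7, and D7 stood at 0.674 of D2 (0.657 to 0.692). This class held 98.2% of the Arg1 UMIs of D2 and 94.3% of D7, whereas in Sham T/NK/ILC-like cells held 90.6%. Thinned, 0 of 1082 Sham cells of the class had an Arg1 UMI, which allows up to 0.277%, against 22.7% at D2 (21.4 to 24.0) and 7.43% at D7 (6.49 to 8.46). Thinning left out 18 D2 and 35 D7 cells, and the unthinned shares were 0.269%, 56.9% and 16.2%, with median depths of 7178, 11273.5 and 8016 UMIs. In B-like cells the thinned Arg1 shares were 0, 0 and 0.134% and the unthinned ones 0, 2.47% and 1.06%. Arg1 was highest in cluster 19, at 1735 CPM in 138 D2 cells and 1113 CPM in 363 D7 cells, with 0 Sham cells. This cluster held 6532 of the 8199 Arg1 UMIs of the class at D7 but 3733 of 22781 at D2. The class ratio of D7 to D2 thus rests largely on its larger share at D7. Between D2 and D7 the level went from 383.1 to 175.4 CPM in cluster 7, from 561.2 to 133.0 CPM in cluster 8 and from 169.3 to 37.7 CPM in cluster 9. In no compared cluster of the class was it higher at D7.

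**Figure D2:**
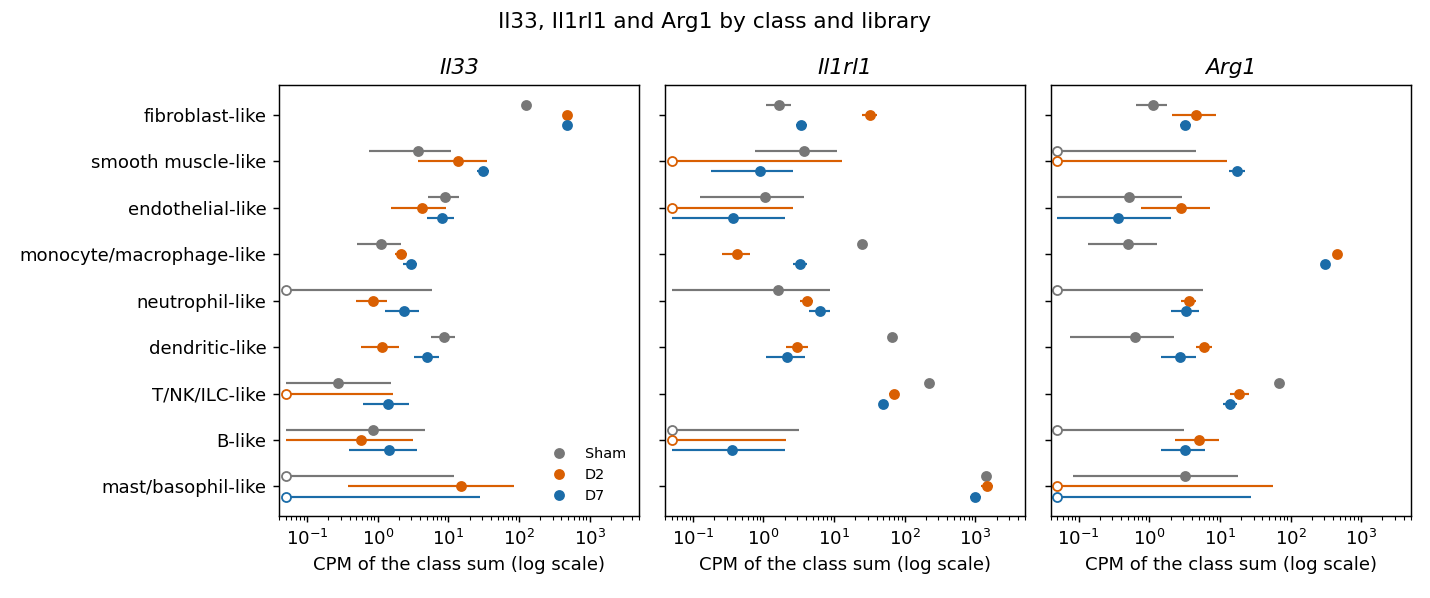
Level of Il33, Il1rl1 and Arg1 (CPM of the class sum, log axis) in 9 cell classes and the Sham, D2 and D7 libraries, with exact 95% Poisson intervals for counting error, open symbols at the left edge for 0 UMIs and intervals drawn from that edge where they reach below it. Il33 stands highest in fibroblast-like cells, at 127.5 CPM in Sham and 472 CPM at D2.

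Fibroblast-like cells at D2 carried high levels of division and myofibroblast transcripts and of some matrix and chemokine transcripts. Those of resting adventitial cells were low. Cthrc1, a secreted protein of activated fibroblasts, stood at 543.7 CPM against 2.66 CPM in Sham, 205-fold higher (151 to 285). The neutrophil chemokine Cxcl5 stood at 165.8 CPM against 0.0618 CPM (1 UMI), a ratio of 2683 (478 to 1.06e+05). The adhesion molecule Chl1 was 235-fold (141 to 423) higher, the matrix glycoprotein Tnc 130-fold (76.9 to 235) and Nt5dc2 92.2-fold (63.4 to 139). Lower at D2 were Opcml, a membrane-anchored adhesion protein (5.09 against 452 CPM, 88.9-fold), Pla1a, a secreted phospholipase (3 UMIs, 117-fold, 40.0 to 567), and Iigp1, an interferon-induced GTPase (68.1-fold, 31.2 to 186).

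Of 22 measured cell cycle genes, 21 were at least 1.5-fold higher at D2 and 0 lower, with a median log2 ratio of 3.06, among them Birc5 (63.6-fold), Ccna2 (56.3-fold) and Ccnb2 (51.5-fold). Of 17 myofibroblast genes, 13 were higher and 1 lower (median 1.57), including Adam12 (30.5-fold) and the contractile actin gene Acta2 (25.4-fold). Stromal chemokines and cytokines had a median of 1.08, with 12 of 20 members higher and 6 lower. Cxcl2, which draws neutrophils, was 5.98-fold and Ccl8 4.89-fold higher, whereas the eosinophil chemokine Ccl11 was 5.04-fold lower. Glycolysis and hypoxia genes had a median of 1.2 (14 of 21 higher, 4 lower), with Pgk1 6.70-fold and Pkm 6.55-fold higher. Extracellular matrix genes had a median of 0.50 (13 of 26 higher, 5 lower), with the collagen crosslinking enzyme Lox 6.62-fold higher. Of 15 genes of the unfolded protein response, 8 were higher and 0 lower (median 0.67), including the chaperone Calr (2.75-fold). Proteases and their inhibitors were mixed, with 7 of 17 higher and 4 lower (median −0.18). Timp1, an inhibitor of metalloproteinases, was 22.2-fold higher, and Timp3 6.13-fold lower.

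On the low side at D2, 12 of 13 adventitial progenitor genes were lower and 0 higher (median −2.05). Dpp4 was 43.5-fold, Pi16 37.5-fold, Scara5 12.99-fold and Clec3b 12.0-fold lower. Interferon response genes had a median of −1.82 (14 of 17 lower, 0 higher), with Gbp2 7.18-fold and Cxcl10 7.17-fold lower. Basement membrane genes had a median of −1.24 (9 of 11 lower, 0 higher), with Nid1 6.61-fold and Lama2 6.36-fold lower. Dissociation response genes, early response transcripts that tissue digestion can induce, had a median of −0.95 (15 of 19 lower, 3 higher), with Atf3 4.16-fold lower. Against random lists the cell cycle, myofibroblast and glycolysis medians lay at percentile 100, stromal chemokines at 99.99, unfolded protein response at 98.0, extracellular matrix at 95.6, proteases at 16.1, basement membrane at 0.0700, dissociation at 0.0200, and adventitial progenitor and interferon genes at 0. By size alone 1143 genes were at least 2-fold apart, 548 higher and 595 lower at D2. With at least 500 genes and 1000 UMIs per cell the cell cycle median was 1.23, and with the mean over cells in place of the sum the basement membrane median was −0.39 and the gene count 614. The neutrophil transcript S100a8 stood at 10.8, 96.6 and 73.1 CPM in Sham, D2 and D7 fibroblast-like cells and at 5.96, 81.1 and 18.2 CPM in B-like cells, a measure of RNA from other cells.

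At D7 fibroblast-like cells had higher levels of matrix and myofibroblast genes than in Sham, and lower levels of adventitial progenitor genes. Cthrc1 stood at 784.5 CPM, 295-fold higher (219 to 408). Tnn, another tenascin, stood at 133.8 CPM against 0.124 CPM (2 UMIs), a ratio of 1083 (299.6 to 8943), and Chl1 was 186-fold higher (113 to 332). Lower were Inmt, a methyltransferase of indoleamines (4.17 against 321.9 CPM, 77.2-fold, 66.1 to 90.8), and Smpd3, a sphingomyelinase (3.38 against 246.9 CPM, 73.2-fold, 61.5 to 87.7).

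Of 17 myofibroblast genes, 14 were higher and 0 lower (median 3.23), with Tnc 107-fold, the cadherin Cdh11 20.1-fold and Adam12 14.8-fold higher. Extracellular matrix genes had a median of 1.61 (17 of 26 higher, 2 lower), with Postn, a matricellular protein, at 2542 against 267.9 CPM (9.49-fold) and Comp 8.50-fold higher. Proteases and inhibitors had a median of 1.35 (11 of 19 higher, 4 lower), with Timp1 7.42-fold and Serpina3n 6.34-fold higher and Adamts5 5.25-fold lower, and the median was 0.47 with free RNA subtracted. Cell cycle genes had a median of 0.68 (12 of 22 higher, 1 lower), with Tubb5 1.99-fold higher. Adventitial progenitor genes had a median of −1.48 (10 of 13 lower, 0 higher), with Dpp4 8.92-fold, Scara5 6.90-fold and Sema3c 5.88-fold lower. Basement membrane genes had a median of −0.98 (7 of 12 lower, 1 higher), with Col4a1 3.06-fold lower. Interferon response genes had a median of −0.52 (8 of 18 lower, 0 higher), with Gbp2 3.13-fold lower. Stromal chemokines split evenly, with 8 of 21 higher and 8 lower (median 0.18), Cxcl2 being 5.68-fold higher and Ccl11 5.52-fold and the B cell chemokine Cxcl13 4.62-fold lower. Glycolysis genes (median 0.22, 6 of 21 higher and 4 lower), dissociation response genes (median −0.18) and the unfolded protein response (median −0.18) differed little, though the hypoxia regulator Hif1a was 4.31-fold higher. Against random lists the matrix, myofibroblast and protease medians lay at percentile 100, cell cycle at 99.99, glycolysis at 98.1, chemokines at 92.6, unfolded protein response at 19.8, dissociation at 14.3, interferon at 0.0900, basement membrane at 0.0200 and progenitor genes at 0. By size 677 genes were at least 2-fold apart, 280.0 higher and 397 lower at D7.

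Between the injured time points, fibroblast-like cells at D7 had more matrix transcripts and far fewer division transcripts than at D2. The collagen-binding proteoglycan Fmod was 49.3-fold (19.2 to 181), the secreted C1qtnf3 36.3-fold (20.8 to 70.2), the fibrillar collagen Col11a1 36.3-fold (18.4 to 84.1), Cpxm2 17.9-fold (10.0 to 35.9) and the growth factor Mdk 15.6-fold (11.1 to 22.7) higher at D7. Lower were Birc5, which blocks apoptosis in dividing cells (20.01-fold, 17.2 to 23.3), the centromeric histone Cenpa (15.5-fold, 13.4 to 18.0) and Pclaf, a replication factor (11.7-fold, 9.89 to 13.8). All 22 cell cycle genes were lower at D7 (median −2.31), as were 13 of 21 glycolysis genes (median −1.03), with Pgk1 5.73-fold lower, and 10 of 15 unfolded protein response genes (median −0.83), with 0 higher in each of these lists. Extracellular matrix genes had a median of 0.84 (16 of 26 higher, 3 lower), with Comp 10.98-fold, Aspn 7.47-fold and elastin (Eln) 7.33-fold higher. Myofibroblast genes had a median of 0.53 (8 of 17 higher, 3 lower), adventitial progenitor genes 0.94 (9 of 13 higher, 0 lower, Pi16 6.62-fold) and basement membrane genes 0.35. Interferon response genes had a median of 0.91 (12 of 18 higher, 0 lower, Isg15 6.14-fold), or 0.85 with a member at 0 UMIs set to its bound. Dissociation response genes had a median of 0.82 (13 of 19 higher, 3 lower). Stromal chemokines were lower (median −0.46, 9 of 21 lower, 1 higher), among them the monocyte chemokine Ccl2 (3.78-fold) and Cxcl5 (4.28-fold). Proteases had a median of −0.03. By size 466 genes were at least 2-fold apart, 246 higher and 220.0 lower at D7. With at least 500 genes and 1000 UMIs per cell the cell cycle median was −0.48, that of progenitor genes 0.12 and the gene count 262.

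Smooth-muscle-like cells were compared between D7 and Sham only, since D2 held 16 of them. At D7 they carried fewer contractile and more matrix transcripts. Spp1, which encodes osteopontin, stood at 2456 CPM against 1.24 CPM (1 UMI), a ratio of 1986 (356 to 7.85e+04), and was seen in 22.2% of D7 cells. Timp1 stood at 881.2 CPM against 1.24 CPM (1 UMI), a ratio of 713 (128 to 2.82e+04), and Fbln2, a fibulin of elastic matrix, at 231.8 CPM against 0 UMIs, at least 62.5-fold higher. The proteoglycan Ogn (53.2 against 626.8 CPM, 11.8-fold, 9.92 to 14.0) and cardiac actin Actc1 (55.6 against 544 CPM, 9.79-fold, 8.23 to 11.7) were lower.

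Of 20 contractile smooth muscle genes, 17 were at least 1.5-fold lower and 0 higher (median −1.27), with the integrin Itga8 6.23-fold, myosin heavy chain Myh11 4.82-fold, calponin Cnn1 4.28-fold and phospholamban Pln 4.07-fold lower. Of 20 genes of smooth muscle modulation, 14 were higher and 1 lower (median 1.44), including the short-chain collagen Col8a1 (11.2-fold). Extracellular matrix genes had a median of 1.54 (19 of 26 higher, 2 lower), with Cthrc1 20.3-fold, Col12a1 14.8-fold and Col1a1 9.20-fold higher. The extracellular matrix median log2 ratio, smooth muscle, D7 over Sham, was 1.64 with free RNA subtracted. Without subtraction matrix genes had medians of 1.28 in neutrophil-like, 1.24 in dendritic-like and 1.09 in T/NK/ILC-like cells too. Proteases had a median of 1.53 (11 of 17 higher, 4 lower), with the collagenase Ctsk 6.61-fold and Mmp14 4.85-fold higher. Basement membrane genes had a median of 0.53, with 6 of 12 higher and 2 lower, Col4a1 by 2.86-fold higher. Cell cycle genes had a median of 3.92 (20 of 22 higher, 0 lower), or 2.30 with the 9 members at 0 UMIs in Sham at their bound, among them Birc5 (at least 23.3-fold) and Top2a (at least 17.1-fold). Stromal chemokines had a median of 1.15 (10 of 19 higher, 4 lower), or 0.24 with 4 members at their bound, with Ccl2 5.11-fold and the macrophage growth factor Csf1 3.92-fold higher. Dissociation response genes had a median of −0.42, with the heat shock gene Hspa1a 8.29-fold lower. Against random lists the contractile median lay at percentile 0, dissociation at 0.580, basement membrane at 98.5 and the other 5 lists at 100. By size 676 genes were at least 2-fold apart, 366 higher and 310.0 lower at D7. With at least 500 genes and 1000 UMIs per cell the cell cycle median was 0.83 and the log2 ratio of Fbln2 2.60, against 7.86 in the main setting.

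Endothelial-like cells at D2, 89 cells against 475 in Sham, carried genes of leukocyte adhesion, proteolysis and division and had lower levels of quiescence genes. Tmem252 was 14.7-fold (11.1 to 19.9), the metalloproteinase Adam12 12.95-fold (8.25 to 21.4), the chemokine-binding receptor Ackr1 11.5-fold (8.30 to 16.3) and the membrane metalloproteinase Mmp14 11.3-fold (7.21 to 18.4) higher. Timp4, an inhibitor of metalloproteinases, was 55.3-fold lower (29.0 to 122), Cytl1, a secreted cytokine-like protein, 11.6-fold (9.74 to 14.0) and Itm2a 11.2-fold (7.26 to 18.1). Of 17 endothelial activation genes, 11 were higher and 3 lower (median 1.23), with the leukocyte adhesion receptors Sele 38.6-fold and Selp 10.5-fold higher and Esm1 12.9-fold lower. Of 20 quiescence genes, 12 were lower and 0 higher (median −1.40), with the arterial gap junction gene Gja5 23.9-fold (3 UMIs, 7.94 to 118), the tight junction gene Cldn5 9.27-fold and the flow-responsive Klf4 5.91-fold lower. Capillary and venous genes had a median of −1.04 (8 of 15 lower, 3 higher), with Btnl9 6.66-fold lower. All 22 cell cycle genes were higher (median 1.93), among them Ccnb2 (15.2-fold) and Mki67 (7.11-fold). Proteases had a median of 1.36 (9 of 14 higher, 4 lower), with Mmp9 at least 42.0-fold and Timp1 17.3-fold higher. Mmp9 is also a neutrophil marker of the fixed set, and the neutrophil transcript S100a8 was higher in these cells too. Neutrophil RNA was therefore not excluded as a source of Mmp9. Unfolded protein response genes had a median of 0.83 (10 of 15 higher, 1 lower) and dissociation response genes −0.90 (13 of 19 lower, 2 higher). Extracellular matrix genes had a median of −1.22 (10 of 18 lower, 4 higher), or −1.05 with 2 members at their bound, with Eln 6.06-fold lower and Col15a1 2.08-fold higher, and the median was 0.00 with free RNA subtracted. Members set to 0 by the subtraction in both libraries also give 0.00. Less matrix RNA from fibroblast-like cells was not excluded for this median. By size 864 genes were at least 2-fold apart, 429 higher and 435 lower at D2. S100a8 stood at 9.35, 417 and 89.0 CPM in Sham, D2 and D7 endothelial-like cells.

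At D7 endothelial-like cells had higher levels of activation and cell cycle genes than in Sham and lower levels of capillary genes. The substance P receptor gene Tacr1 was 28.7-fold (14.4 to 67.1) and Cmah, an enzyme of sialic acid synthesis, 20.4-fold (14.1 to 30.6) higher than in Sham, and Timp4 23.9-fold (17.4 to 33.8) and the retinol-binding protein gene Rbp7 14.9-fold (12.3 to 18.3) lower. Endothelial activation genes had a median of 0.67 (9 of 16 higher, 2 lower), with Sele 33.8-fold, Angpt2, an antagonist of vessel stability, 5.72-fold and Selp 5.46-fold higher. Quiescence genes had a median of −0.24 (7 of 20 lower, 1 higher), with Klf4 4.53-fold lower and the gap junction gene Gja4 3.68-fold higher. Capillary and venous genes had a median of −1.17 (8 of 15 lower, 3 higher), with carbonic anhydrase Car4 8.94-fold and Tcf15 5.66-fold lower. Cell cycle genes had a median of 1.23 (20 of 22 higher, 0 lower), extracellular matrix genes 0.95 (18 of 26 higher, 4 lower, Col3a1 4.36-fold) and proteases 1.5 (11 of 16 higher, 3 lower, Mmp14 14.6-fold). Dissociation response genes had a median of −0.92 and the unfolded protein response 0.06. With free RNA subtracted the protease median was 0.20 and the matrix median 0.00, which members set to 0 in both libraries also give. Matrix RNA from fibroblast-like cells was not excluded. By size 495 genes were at least 2-fold apart, 223 higher and 272 lower at D7.

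Set against D2, endothelial-like cells at D7 had higher levels of quiescence genes and lower levels of cell cycle genes. The sodium-calcium exchanger gene Slc8a1 was 7.76-fold (5.61 to 11.02), Igfbp3, which binds insulin-like growth factors, 6.32-fold (4.95 to 8.19), Stmn2 3.32-fold and Cmah 3.21-fold (2.68 to 3.88) higher. Pclaf was 2.82-fold, Ddx39 2.70-fold and AI506816 2.56-fold lower. Extracellular matrix genes had a median of 1.51 (21 of 25 higher, 0 lower), with Col3a1 44.5-fold (20.3 to 122), Col1a1 42.2-fold (16.3 to 156) and Col1a2 at least 37.3-fold higher, and 0.00 with free RNA subtracted. Here too members set to 0 in both libraries give 0.00. RNA from fibroblast-like cells was not excluded as a source of these collagen transcripts. Quiescence genes had a median of 0.64 (11 of 20 higher, 0 lower), with Gja5 34.7-fold (11.7 to 170), Cldn5 4.76-fold and the Notch ligand Dll4 2.93-fold higher. Cell cycle genes had a median of −0.79 (14 of 22 lower, 0 higher), unfolded protein response genes −0.64 (8 of 15 lower, 0 higher) and proteases 0.43, with Mmp9 12.8-fold lower. The neutrophil transcript S100a8 was lower as well, at 417 CPM at D2 and 89.0 CPM at D7, so less neutrophil RNA was not excluded for Mmp9. Endothelial activation genes had a median of −0.19, with the invariant chain gene Cd74 9.04-fold higher and Selp 1.92-fold lower, capillary and venous genes −0.14 and dissociation response genes 0.05. Over the 3 endothelial comparisons (D2 over Sham, D7 over Sham, D7 over D2) the percentiles among random lists were 100, 100 and 10.6 for activation, 0, 1.33 and 100 for quiescence, 0.0100, 0 and 17.0 for capillary and venous genes, 100, 100 and 0 for the cell cycle, 0, 100 and 100 for the matrix, 100, 100 and 99.8 for proteases, 100, 51.9 and 0 for the unfolded protein response, and 0, 0 and 64.4 for dissociation. By size 137 genes were at least 2-fold apart, 90.0 higher and 47 lower at D7.

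Monocyte/macrophage-like cells at D2 had low levels of resident macrophage genes and high levels of glycolysis and lipid-associated macrophage genes. Spp1 stood at 1300.0 CPM against 1.00 CPM, 1298-fold higher (658.7 to 3007), and Arg1 was 910.5-fold higher (356 to 3342). Mmp14 was 46.3-fold (30.2 to 74.8), the laminin receptor Itga6 45.6-fold (31.1 to 69.9) and the matricellular Thbs1 24.7-fold (22.4 to 27.2) higher. Retnla, an alternative activation marker, stood at 8.81 against 6542 CPM, 742.8-fold lower (676 to 818). Timd4, a receptor for dying cells on resident macrophages, was 643.5-fold (325 to 1495) and the lectin Cd209f 122-fold (101 to 148) lower.

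Of 15 resident macrophage genes, 12 were lower at D2 and 1 higher (median −2.11), with the hyaluronan receptor Lyve1 52.4-fold lower. Alternative activation genes split, with 11 of 18 lower and 5 higher (median −0.91), the lectin Mgl2 being 52.4-fold and the haemoglobin scavenger receptor Cd163 11.8-fold lower while Arg1 was higher. Lipid-associated macrophage genes had a median of 0.94 (10 of 17 higher, 3 lower), with Fabp5, a fatty acid carrier, 17.5-fold and Trem2 13.6-fold higher and the scavenger receptor Cd36 8.71-fold lower. Of 21 glycolysis and hypoxia genes, 17 were higher and 0 lower (median 1.18), with Vegfa 11.1-fold and Hif1a 4.64-fold higher. Inflammatory cytokines and chemokines had a median of 0.36 (6 of 19 higher, 3 lower), or 0.31 with a member at its bound. Cxcl3 was 4.20-fold, Osm 3.56-fold and Ptgs2, which makes prostaglandins, 3.39-fold higher, and Il6 9.39-fold lower. Growth factors had a median of −0.53 (7 of 18 lower, 4 higher), with Hbegf 8.66-fold, Igf1 7.41-fold and Gas6 4.39-fold lower, and 0.15 with free RNA subtracted. The share subtracted was estimated at 24.55% in Sham against 2.55% at D2, so 0.15 may reflect too large a subtraction in Sham. Antigen presentation genes had a median of −0.60 (7 of 14 lower, 0 higher), with Cd74 2.26-fold lower. Oxidative stress and iron genes had a median of 0.19 (6 of 17 higher, 7 lower), interferon response genes 0.29 (2 of 18 higher, 3 lower) and dissociation response genes −0.35 (7 of 19 lower, 2 higher). Cell cycle genes had a median of 0.52 (10 of 22 higher, 0 lower), which was −0.39 at resolution 0.5 and −0.11 over members of at least 50 CPM. Cluster 31, with Top2a, Birc5 and Stmn1 among its leading genes, scored best as monocyte/macrophage but stayed without a class. Its 24 Sham, 37 D2 and 81 D7 cells are left out of this class, so its cell cycle values in every comparison depend on the naming rule. By size 479 genes were at least 2-fold apart, 206 higher and 273 lower at D2.

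At D7 Spp1, at 1304 CPM, was 1302-fold (660.7 to 3016), Arg1 614-fold (240.0 to 2254) and Clec4n, which encodes the fungal receptor dectin-2, 30.8-fold (25.7 to 37.0) higher than in Sham, and Retnla 172-fold and Timd4 110-fold (73.9 to 171) lower. These ratios and those of D2 share the Sham library, so they are not independent. Resident macrophage genes had a median of −2.28 (13 of 15 lower, 0 higher), with Cd209f 30.8-fold and Lyve1 25.9-fold lower, and alternative activation genes −0.76 (10 of 18 lower, 3 higher), with Cd163 15.8-fold and Ccl24 14.9-fold lower. Lipid-associated genes had a median of 1.41 (13 of 17 higher, 2 lower), with Fabp5 25.5-fold, the macrophage elastase Mmp12 24.8-fold and Trem2 9.45-fold higher. Inflammatory genes had a median of 0.85 (12 of 19 higher, 2 lower), with Cxcl3 26.8-fold, the interleukin 1 antagonist Il1rn 6.57-fold and Il1b 5.22-fold higher. Glycolysis genes had a median of 1.24 (14 of 21 higher, 1 lower), with Pkm 3.19-fold higher, and oxidative stress and iron genes 0.82 (10 of 17 higher, 4 lower), with the cystine transporter Slc7a11 6.77-fold and ferritin heavy chain Fth1 4.06-fold higher. Cell cycle genes had a median of 1.24 (18 of 22 higher, 0 lower), Stmn1 being 3.33-fold higher, again without the dividing cells of cluster 31. Growth factors had a median of −0.06, with Vegfa 10.4-fold and Osm 4.36-fold higher, antigen presentation −0.37 (3 of 14 lower, 0 higher), interferon response −0.12 and dissociation response −0.43. By size 564 genes were at least 2-fold apart, 244 higher and 320.0 lower at D7. The cell cycle median was 0.60 with at least 500 genes and 1000 UMIs per cell.

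D7 and D2 were closer to each other, with 71 genes at least 2-fold apart, 52 higher and 19 lower at D7. Scaling by the median of ratios moved all log2 ratios of this comparison by 0.11. Mmp12 was 30.2-fold (26.3 to 34.9), Cxcl3 6.39-fold (6.12 to 6.67), lipoprotein lipase (Lpl) 6.10-fold, the stress cytokine Gdf15 4.52-fold and haem oxygenase (Hmox1) 2.89-fold higher at D7, and the chitinase-like Chil3 3.56-fold, fibronectin (Fn1) 3.35-fold and Rnase4 2.89-fold lower. Oxidative stress and iron genes had a median of 0.83 (10 of 17 higher, 0 lower), with the iron exporter Slc40a1 9.46-fold and Gclm, of glutathione synthesis, 2.74-fold higher. Growth factors had a median of 0.41 (7 of 18 higher, 1 lower), with Igf1 6.48-fold and Areg 4.27-fold higher. Inflammatory genes had a median of 0.42 (9 of 20 higher, 0 lower, Il1rn 2.44-fold), lipid-associated genes 0.31 (6 of 17 higher, 1 lower, Cd9 3.94-fold), antigen presentation genes 0.21 (5 of 14 higher, 0 lower, H2-Eb1 1.85-fold) and cell cycle genes 0.68 (13 of 22 higher, 0 lower). Resident macrophage genes had a median of −0.41 (6 of 15 lower, 4 higher), with Cbr2 2.40-fold and Stab1 2.35-fold lower. Alternative activation genes had a median of 0.01 (7 of 18 higher, 4 lower, Mgl2 8.47-fold higher), interferon response −0.32, glycolysis −0.08 and dissociation response −0.01. Over the 3 monocyte/macrophage comparisons in the same order as above, the percentiles were 0, 0 and 0.0200 for resident, 0, 0 and 80.3 for alternative activation, 98.4, 100 and 100 for inflammatory, 100 in each for lipid-associated and cell cycle, 0.05, 51.8 and 100 for growth factor, 0.0400, 3.40 and 99.6 for antigen presentation, 100, 100 and 50.6 for glycolysis, 84.3, 100 and 100 for oxidative stress, 96.8, 46.3 and 0.280 for interferon and 0.290, 0.450 and 58.3 for dissociation genes. Monocyte/macrophage-like cells of the 3 libraries came from different clusters, so these ratios compare mixtures of states.

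**Figure D3:**
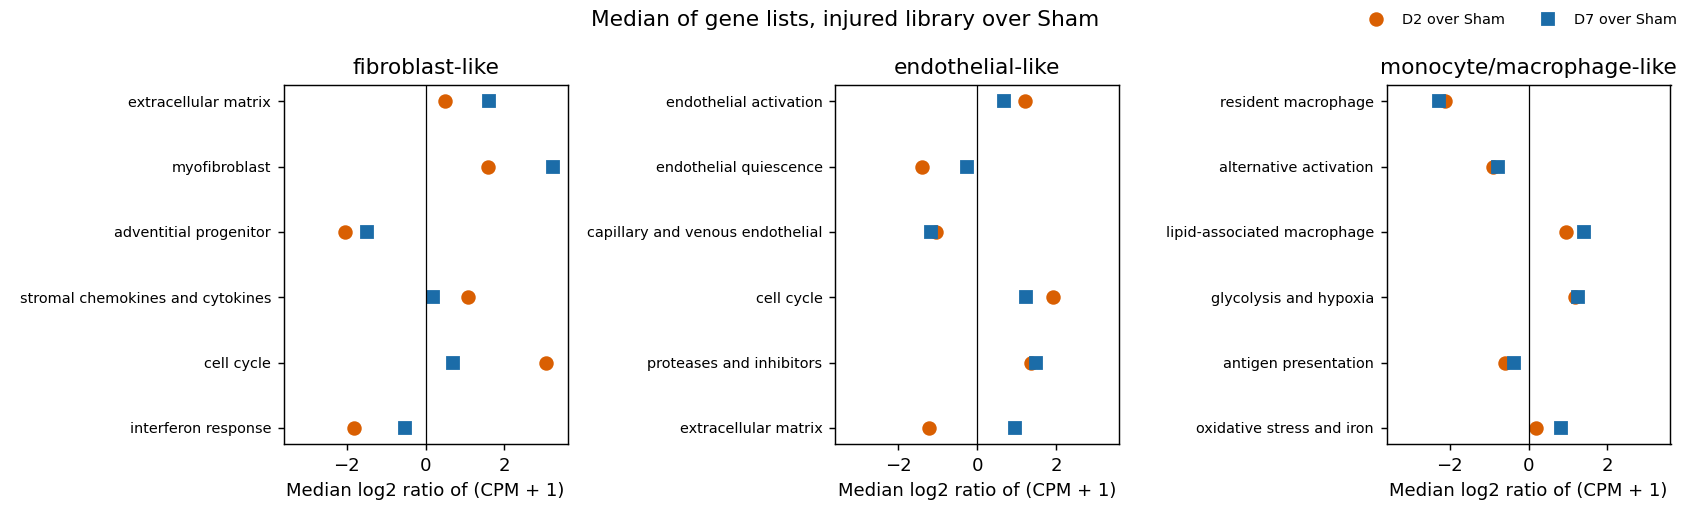
Median log2 ratio of (CPM + 1) of fixed gene lists (linear axis) in fibroblast-like, endothelial-like and monocyte/macrophage-like cells, circles for D2 over Sham and squares for D7 over Sham, with 1 library per group and no error bars. Myofibroblast genes stand at 1.57 and 3.23 in fibroblast-like cells, and resident macrophage genes at −2.11 and −2.28 in monocyte/macrophage-like cells.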

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

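Of the tests in this part, those of free RNA and of a few cells were chosen after the result had been seen. The results here stood out because a ratio between 2 libraries pointed one way at one time or in one cell class and the opposite way in another. With 1 library per group none of these differences was tested.

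Extracellular matrix genes in endothelial-like cells had a median log2 ratio to Sham of −1.22 at D2 and 0.95 at D7, and of 0.00 at both times with free RNA subtracted. Members that the subtraction sets to 0 in both libraries have a log2 ratio of 0. The 0.00 therefore does not show that the difference went away. Matrix genes went the same ways in neutrophil-like cells. Their medians were −1.84 at D2 (10 of 14 lower, 3 higher) and 1.28 at D7 (13 of 21 higher, 1 lower). Matrix RNA from fibroblast-like cells was thus not excluded as a source of the endothelial values.

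Il1rl1, the gene of the IL-33 receptor, went opposite ways in fibroblast-like and monocyte/macrophage-like cells in each comparison. The ratios were 19.2 against 0.0168 for D2 over Sham, 2.07 against 0.132 for D7 over Sham and 0.108 against 7.85 for D7 over D2.

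The high Il1rl1 level in D2 fibroblast-like cells was weighed further. The tables argue against free RNA, since 32.04 CPM (24.6 to 41.0) lay above the 4.99 CPM of the whole library. They also argue against doublets with mast cells or lymphocytes among the 11 Il1rl1-positive cells as a set. Of these, 0 held UMIs of 2 or more of their markers (upper bound 28.5%). The 3 cells with most Il1rl1 UMIs are among the 11, but a bound for them alone would be far wider. For those 3 cells the test cannot decide. Pooled with smooth-muscle-like cells, the lowest ratio over the cell and class settings was 5.32 (3.23 to 8.60). The border between these classes alone thus cannot account for the pooled rise, although with a class per cell 29 of the 63 UMIs stayed in these 2 classes. Pooling cannot show which class holds the signal. With at least 500 genes and 1000 UMIs per cell the pooled ratio was 14.3 with 63 UMIs. That of fibroblast-like cells alone was far lower, as given above. The level rested on a few cells, since 3 cells held 55 of the 63 UMIs against 9 to 15 (95% range) when the UMIs were drawn by depth, and without them, a choice that fixes the direction, the ratio was 2.67 (1.05 to 6.05). These cells had 46392 to 68818 UMIs each against a class median of 8927.5, and doublets with neutrophils or other cells were not tested. Whether they are such doublets, a rare state after injury or another cell type named with fibroblasts stays open, and injury itself was not tested as a cause.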

How the results depend on the processing

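Leaving out the low-depth fibroblast-like cluster of Sham was an alternative chosen after seeing the data, and the others were planned. No paired analysis was possible because each group is 1 pooled library. Share ratios, key gene ratios and thinned shares were called moved when outside the 95% interval of the main value, which holds counting error only, and gene counts, list medians and named genes when more than 1.5 times from it. Share ratios kept their value in 45 cases, moved in 32 and reversed in 3. Gene counts kept it in 116 and moved in 14, key gene ratios in 155 and 33, list medians in 1210 and 63, named genes in 675 and 73 and thinned shares in 6 and 12. No named gene reversed, and small list medians were not judged for direction. Free RNA was not subtracted over the whole library, a class with too few cells under a setting gave no value, and the values of further classes in the last part were not recomputed. Apart from the lower gene minimum, which by construction admits more genes, the cause was not tested. Few cells limit the D2 stroma (112 fibroblast-like, 89 endothelial-like and 16 smooth-muscle-like cells), and depth limits Sham, with medians of 1873 UMIs in fibroblast-like, 3454 in endothelial-like and 4423 in smooth-muscle-like cells.

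Values below are ratios to Sham unless a comparison is named. With at least 500 genes and 1000 UMIs per cell, Il33 in fibroblast-like cells was 4.415 at D2, the shares were 0.4811 (endothelial, D7), 0.01543 and 0.8179 (fibroblast, D2 and D7), 16.79 and 5.74 (neutrophil) and 0.4396 (smooth muscle, D2), and 262 fibroblast genes were apart between D7 and D2. With at most 10% mitochondrial UMIs the monocyte/macrophage share at D2 was 2.894. With a class per cell the shares were 0.1595 (endothelial, D2), 0.6064 (fibroblast, D7), 4.298 and 2.451 (monocyte/macrophage, D2 and D7), 0.2625 (smooth muscle, D2) and, reversed, 0.7734 (smooth muscle, D7), and 1076 smooth muscle genes were apart. With doublets kept the monocyte/macrophage shares were 2.879 and 1.855. With each library clustered on its own the fibroblast shares were 0.02558 and 0.6902 and the smooth muscle share at D2 was 0.4118. At resolution 2 the fibroblast shares were 0.03048 and 0.9746, monocyte/macrophage 3.602 and 2.247, neutrophil 16.33 and 5.356, and smooth muscle 0.03145 at D2 and, reversed, 0.7079 at D7. Il33 in fibroblast-like cells at D7 was 3.527 there, and 1114 smooth muscle genes were apart. Without the low-depth cluster the shares at D2 and D7 were 0.09237 and 0.4104 (endothelial), 0.0251 and 0.8173 (fibroblast), 1.907 and 1.277 (monocyte/macrophage) and 15.02 and 5.246 (neutrophil), and the smooth muscle share at D7 reversed to 0.9743. With free RNA subtracted, at a share estimated far higher in Sham (24.0%) than at D2 (2.68%), Il33 in fibroblast-like cells was 3.291 and 3.503. With the mean over cells it was 4.054 at D7, Il1rl1 over the whole library was 0.1621 and 0.2706, and 614 fibroblast genes were apart at D2. With no CPM minimum the gene counts for D2 over Sham, D7 over Sham and D7 over D2 were 3357, 2226 and 1863 in fibroblast-like, 1859, 1380.0 and 675 in endothelial-like and 1620.0, 1726 and 396 in monocyte/macrophage-like cells, and 1792 for D7 over Sham in smooth-muscle-like cells.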

Other observations

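Neutrophil-like cells differed between Sham and injury in state as well as in share of kept cells. These genes come from the named-gene rule applied to further classes, which were chosen after the main results had been seen. Il1a, an early alarm cytokine, stood at 673.2 CPM at D2 against 14.3 CPM in Sham, 47.1-fold higher (24.8 to 103), and 60.6-fold higher at D7. Scimp, an adaptor of pattern receptors, was at least 29.0-fold higher at D2 with 0 UMIs in Sham, and Klhl6 39.97-fold. Retnlg stood at 213.8 against 6055 CPM, 28.3-fold lower, and Scrg1 24.5-fold and Rasgrp2 17.6-fold lower. Inflammatory cytokines and chemokines had a median log2 ratio of 2.83 at D2 (16 of 18 higher, 1 lower) and 2.39 at D7, and interferon response genes 1.32 at D7 (13 of 17 higher, 0 lower). At D7 the interferon-induced Cxcl10 was 4.06-fold, the checkpoint ligand Cd274 3.19-fold and Isg15 2.95-fold higher than at D2, and Klhl6 5.92-fold lower. In Sham 136 of 148 such cells lay in cluster 13, whereas at D2 2003 lay in cluster 0 and 2031 in cluster 1.

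Dendritic-like cells of Sham lay mostly in cluster 21, led by Clec9a and Xcr1 of cross-presenting cells (248 cells), and those of D2 in cluster 11, led by Klrd1 and Cd209a (704 cells). Ifitm1 stood at 4432 CPM at D2 against 40.6 CPM in Sham, 109-fold higher, and Spon1 was 68.6-fold higher, while Cd163 was 34.98-fold and the metallothionein Mt2 27.8-fold lower. In lymphatic-endothelial-like cells Tnc was 19.7-fold and Serpina3n 10.8-fold higher at D7 than in Sham, and Igfbp5 10.2-fold lower (341.4 against 3487 CPM). In T/NK/ILC-like cells Dach2 was 10.04-fold and Cntn1 22.4-fold lower at D2 than in Sham, both leading genes of cluster 29, and cell cycle genes had a median of −1.85. Schwann-like cells had 82 Il33 UMIs at D7 (230.4 CPM, in 8 of 40 cells) and 0 UMIs in Sham. The neutrophil transcript S100a8 was found in 2.16%, 24.2% and 6.52% of B-like cells of Sham, D2 and D7, and haemoglobin Hbb-bs stood at 250.2, 8.96 and 123.3 CPM over the whole libraries.

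In the tests that follow, those of the low non-immune share and that of depth for Il33 were chosen after the result had been seen, and those of fibroblast states and of Il1rl1 over the whole library before it, though for states and clusters the need for a change within a cluster whose bound passes 2-fold was set after their values had been seen.

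Non-immune cells made up 65.2% of Sham and 2.31% of D2 cells. Dilution by leukocytes alone is argued against, since it would leave the mix of non-immune cells as it was, and 44.09% of them were fibroblast-like at D2 (37.9 to 50.4) against 79.3% in Sham. Lost barcodes are argued against too: if all 1047 removed or unnamed D2 barcodes were non-immune, the class would reach 11.13% of barcodes against 61.96% in Sham. Loss of stromal cells in dissociation or sorting stays open, because with 1 library per group it cannot be told apart from a loss in the artery. Such a loss could differ by class, and death of stromal cells after injury was not tested.

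Il33 was higher in fibroblast-like cells after injury. Greater depth is argued against, since at equal depth 33.01% of D2 cells (24.1 to 43.0) had an Il33 UMI against 11.1% in Sham (upper bound 12.4%). Whether more cells of other fibroblast states account for it cannot be told apart from a rise within states. In clusters 10 and 12, deeper clusters that mostly held Sham cells, the Il33 ratio of D7 to Sham was 1.48 together (1.26 to 1.72), against 3.71 for the class, but 1.84 in cluster 10 (1.501 to 2.25) and 1.15 in cluster 12 (0.889 to 1.47), and in the shallow cluster 2 the levels were 101.9 CPM (55.7 to 171) and 89.57 CPM (77.1 to 103.5). The bound set beforehand, a lower end above 1 for both clusters together, was thus met, but it was wrong for this design, since the interval holds only counting error of 1 library per group and cluster 12 alone does not pass it, and injury itself was not tested as a cause.

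Il1rl1 over the whole library was 0.113 of Sham at D2 (0.101 to 0.125) and 0.166 at D7 (0.152 to 0.182). One hypothesis was that the shares of the cell classes account for this. With Sham levels in each class, the shares of UMIs would give 0.651 and 0.607, far above the observed ratios. With Sham levels in each cluster of at least 20 Sham cells they would give 0.141 and 0.205, and for the mean over cells 0.164 and 0.282 against observed 0.162 and 0.271, so cluster shares come close. Shares of these clusters alone, with Sham levels kept inside each, are still argued against. Within cluster 21 of dendritic-like cells Il1rl1 was 0.0242 of Sham at D2 (0.00495 to 0.0717) and 0.0313 at D7. Within cluster 14 of monocyte/macrophage-like cells it was 0.0349 and 0.0893. A different mix of states inside a cluster was not excluded, since Arg1 in cluster 14 went from 0 UMIs in Sham to 165.6 CPM at D2. Not all clusters fell so far: at D7 the ratio was 0.794 in cluster 29 (0.676 to 0.929) and 0.503 in cluster 16 (0.134 to 1.33), and in cluster 32 of T/NK/ILC-like cells Il1rl1 was higher, at 32.3 CPM in Sham (13 to 66.6), 84.9 CPM at D2 (52.5 to 129.7) and 102.6 CPM at D7 (75.9 to 135.6). Whether injury, a different mix of states or a difference between single libraries changed the level within clusters stays open.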
